A study of Mus musculus with 12 samples.

How the data were processed

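The series measured polyadenylated RNA of whole mouse cerebellum at postnatal day 14, with 3 WT and 3 EED-/- libraries on the C57BL/6 strain, prepared with an Illumina RNA-seq kit after Trizol extraction, per the labels' protocols. A further 6 samples are ChIP-seq of H3K27ac, H3K27me3 and input with 1 library per mark and genotype; they were not analysed here. Groups and replicate numbers came from the sample titles and genotype labels.

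The deposited table of estimated counts holds 1 value per gene and library for 55385 versioned Ensembl mouse genes. The deposited counts are expected counts, not scaled between libraries: 22.5% to 23.6% of all values in a library were not whole to within 1e-06, and each column summed to its own total. The submitters' processing notes name Trimmomatic 0.36, Salmon 1.1.0, DESeq2 1.26.0, Bowtie2 2.4.1 and MACS2 and the mouse builds GRCm38 and mm10, without saying which step each served for which assay. Salmon assigns reads to transcripts by likelihood and splits reads shared by similar genes, so values of near-identical paralogues depend on that model. Whether strand was used is not given in the sources used here. The authors' deposited table of differences holds a log2 fold change of EED-/- over WT, a p-value and an adjusted p-value per gene; per the file headers its columns are those of a DESeq2 results table. In it the deposited adjusted p-value was 1 for 20212 genes whose p-value was missing, and those genes were not counted as called or as tested by the authors. Gene symbols came from the same table. Positions came from the GENCODE annotation of GRCm38, matched by unversioned Ensembl identifier for 18076 of 18091 tested genes (99.9%).

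From these files, estimated counts were rounded to whole numbers, and genes were kept by edgeR's filterByExpr on the 2 groups, which left 18091 of the 35196 genes with at least 1 count. TMM factors were 0.966 ± 0.015 in WT and 1.03 ± 0.0208 in EED-/- libraries (SD, n = 3). Differences were tested with edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest, robust) in R 4.3.3, with genotype as the only term, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. SEs of log2 fold changes are the absolute change divided by the square root of F. Gene lists were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, for lists of at least 3 tested genes; alternatives were camera with an estimated correlation and fry. For each list, calls are given over all genes and adjusted over the list alone. Where a group had 0 counts, the fold is a bound against a floor of 3 counts summed over the group; with 1 to 3 counts, a ratio with a 95% exact conditional binomial interval is given. Both cover counting error only, since the counts are of amplified reads without molecular identifiers. With 19621814 to 20366173 counts per library, 1 CPM is about 20 counts, so values of genes under 1 CPM rest on few counts.

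The design, the 33 gene lists (745 genes), the alternatives and the rule for named genes were fixed before the data were examined. The rule took Eed, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between genotypes. It left out gene-model and clone symbols, mitochondrial genes and marked pseudogenes. It then took up to 4 called members of each list with the smallest adjusted p, or the member with the smallest p if none was called. Other genes were named after their values were seen, to complete short counts or to describe lists: E2f1, Bbc3, Peg13, Kcnk9, Ccnd1, Smo, Nxph1, Gfap, Ntsr2, Gja1, Scn3a, Cacna1h, Kcnc2, Kcna4, Grin3a, Grik4, Grid1, Gria1, Grin1, Sfrp4, Smad7, Ier2, Bdnf, Rsad2, Slc17a6, En1, Hoxa9, Hoxa10, Hoxb9 and Hoxb13, and all genes of the closing section that the report does not name. Some called members of short counts are not reported here by name. A further 6 lists were written after the data were examined and are used only in the closing section: skeletal muscle, activated microglia, cholesterol synthesis, germline genes, isthmus genes and nuclear-encoded respiratory chain genes.

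Replicates were compared before averaging. Counts of every replicate pair differed by more than sampling noise (chi-square per degree of freedom 9.11 to 61.4), so none was treated as the same library deposited again. This does not show that they came from separate animals. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.971 to 0.984 within and 0.943 to 0.957 between genotypes. The whole procedure was tested on simulated counts with the library sizes of the real EED-/- and WT libraries. Gene means were taken over all libraries of both genotypes together, and 200 genes were changed. In it 17725 genes passed the filter. It called 59% of genes changed 2-fold and 93% of those changed 4-fold in the right direction, and 8 of its 160 calls were unchanged genes. It called the changed list and 0 of 30 unchanged lists. Its genes were drawn independently of each other, so this does not show how the list test behaves with correlated genes.

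Alternatives were RLE size factors, upper-quartile scaling and library size alone in place of TMM; no low-count filter; at least 10 counts in 3 libraries; DESeq2 1.42.0; limma-voom; the replicate number as a block; each library left out in turn; mitochondrial genes left out; a log2 change beyond 1; and an adjusted p under 0.01. Removal of the transcript length or GC trend of each library by loess (span 0.5) was added after the data were examined.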

Results

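RNA-seq of the mouse cerebellum at postnatal day 14 compared 3 wild-type (WT) libraries with 3 libraries from EED-/- conditional knockouts on the C57BL/6 background. Eed encodes a core subunit of Polycomb repressive complex 2 (PRC2), which places the repressive mark H3K27me3 on histone H3. The comparison asked which transcripts of the cerebellum differ in Eed conditional knockouts; the labels give neither the Cre driver nor the deleted exons. The libraries held 19621814 to 20366173 estimated counts each, and 18091 of the 55385 listed genes had enough counts to be tested. The series also holds 6 ChIP-seq samples (H3K27ac, H3K27me3 and input, 1 of each per genotype), which were not analysed here. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries. Values are CPM, read counts scaled to the library total, after TMM scaling, as mean ± SD over n = 3 libraries per genotype. Adjusted p-values are from edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes.

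Eed itself was lower in every EED-/- library, which checks the genotype labels. Its expression was 20.1, 26.6 and 23.5 CPM in WT replicates 1, 2 and 3, and 11.6, 9.31 and 11.3 CPM in EED-/- replicates 1, 2 and 3. The means of 23.4 ± 3.23 and 10.7 ± 1.23 CPM gave a log2 fold change of -1.12 (SE 0.154, adjusted p = 0.0015), a 2.18-fold lower level. Eed (ENSMUSG00000030619.10) lies on the minus strand of chromosome 7 at 89954654 to 89980983 in GRCm38. Remaining reads can come from cells that kept the gene or from exons outside the deletion, and gene-level counts do not separate these.

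The genotypes separated along the first principal component, which held 55.7% of the variance. In all, 4669 genes differed, 2125 higher and 2544 lower in EED-/- cerebellum, and 1044 of the higher and 832 of the lower genes changed at least 2-fold. Among the called genes 99.8% had no overlap between the WT and EED-/- libraries, against 43.9% of all tested genes and 10% by chance. With 3 libraries per genotype a call nearly requires no overlap, so the 99.8% is not separate support for the calls. Higher genes made up 45.5% of the calls with TMM, but 61.3% with upper-quartile scaling and 58.6% with library size alone. Those scalings moved the median log2 change of all genes up by 0.116 and 0.1, so small changes below are relative to the TMM baseline. Leaving out WT replicate 3, EED-/- replicate 1 or EED-/- replicate 2 reduced the higher genes to 1324, 1205 and 1337. Leaving out WT replicate 3 or EED-/- replicate 1, 2 or 3 reduced the lower genes to 1640, 1335, 1731 and 1677. Without WT replicate 1 or 2 the lower genes numbered 2060 and 2476. Mitochondrial transcripts took 7.22 ± 0.797% of counts in EED-/- and 4.93 ± 1.6% in WT libraries, with WT replicate 1 the lowest at 3.21%. The 50 most abundant genes took 15 ± 0.666% and 12.2 ± 1.29%. Both differences had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow.

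The genes with the largest rises were homeobox genes, the tumour suppressor locus Cdkn2a and genes of skeletal muscle. Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes the cell cycle inhibitors p16Ink4a and p19Arf, rose from 2 counts over the 3 WT libraries to 261 counts, or 4.15 ± 0.86 CPM. The ratio was 119, with a 95% counting interval of 32.7 to 991 (adjusted p = 8.06e-05). Hoxd8 rose from 1 to 429 counts and Hoxd9 from 1 to 125 counts. Hoxa13, Hoxc10 and Vax2, a homeobox gene of eye and forebrain, had 0 counts in WT libraries and were at least 33.2-fold, 29.3-fold and 21.4-fold higher, taking 3 counts over the WT group as the floor. The embryonic and perinatal myosin heavy chains Myh3 and Myh8 rose from 0.455 ± 0.276 to 27.4 ± 6.24 CPM and from 0.384 ± 0.066 to 26.9 ± 6.75 CPM. The muscle creatine kinase Ckm and the subunits Chrng and Chrnd of the fetal muscle acetylcholine receptor were among the same 12 genes, Chrnd at least 21-fold higher. Intervals and floors cover counting error only. Among the 12 largest falls were genes of granule neurons. The cerebellin Cbln3 fell from 786 ± 128 to 42.7 ± 21.3 CPM, the protocadherin-related Fat2 from 1095 ± 236 to 82.4 ± 26.2 CPM, and the GABA-A receptor subunit Gabrd from 112 ± 27.8 to 7.15 ± 1.92 CPM. Dao, which encodes D-amino acid oxidase, fell 17-fold, and Tbata, Il20rb, Crtam, Scnn1g, Tssk5, Ly6d and Chil5 fell 13.2-fold to 18-fold. Spag17os is an antisense transcript and its 18.2-fold fall is uncertain, because strand-specific counting is not stated.

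**Figure D1:**
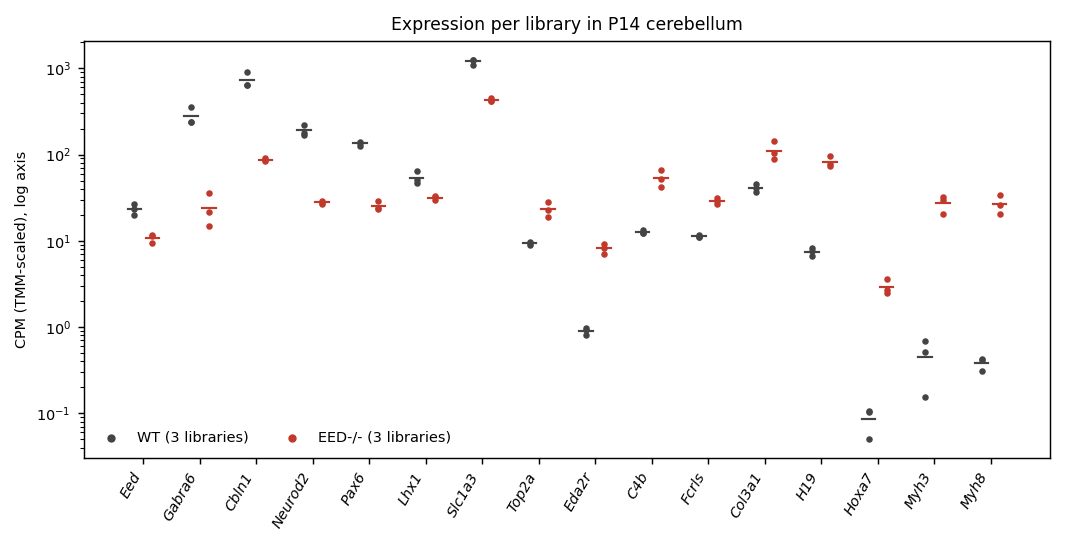
Expression of 16 genes in each library on a log axis of TMM-scaled CPM, WT libraries in grey and EED-/- libraries in red; points are single libraries and short lines the means of 3. Eed fell 2.18-fold, granule neuron genes such as Gabra6 (11.6-fold) and Cbln1 (8.39-fold) fell further, and Myh3 rose from 0.455 to 27.4 CPM. All genes shown were taken from the called genes, and none overlapped between the genotypes.

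Of 33 gene lists fixed before the data were examined, 32 had at least 3 tested members. By limma's camera with a preset inter-gene correlation of 0.01, 17 lists were higher and 3 lower in EED-/- than other genes. None of these 20 passed with a correlation estimated from the residuals, where the smallest adjusted p was 0.148, and fry called 25 lists. The per-gene counts below therefore carry each statement, and the list p-values follow them. Over all 18091 tested genes 2125 were higher and 2544 lower, so a count near these shares is not particular to its list. Such counts include 4 of 26 Purkinje markers lower, 2 of 17 choroid plexus and ependymal genes higher, and 2 of 20 cholesterol synthesis genes lower. Others are the higher counts of 2 of 17 immediate early genes, 3 of 22 markers of Bergmann glia and astrocytes, and 5 of 32 voltage-gated ion channels. Adjusted p-values of lists are Benjamini-Hochberg values over the 32 lists.

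Markers of granule neurons, the most abundant neurons of the cerebellum, fell in nearly every case and had the lowest median of the 32 lists. Of 23 tested markers 21 fell and 0 rose (22 fell when adjusted over the list alone), with a median log2 change of -2.41. The GABA-A receptor subunit Gabra6 (chromosome 11, 42306437 to 42321072) fell from 280 ± 67 to 24 ± 10.6 CPM (log2 fold change -3.54, SE 0.335, adjusted p = 0.000436). The synaptic organiser Cbln1 fell from 730 ± 152 to 87 ± 3.23 CPM, the NMDA receptor subunit Grin2c from 258 ± 17.7 to 38 ± 3.18 CPM, and the transcription factors Neurod2 and Zic1 fell 6.82-fold and 5.32-fold. The camera adjusted p was 5.02e-17, and the adjusted p was 0.148 with an estimated correlation. Among 17 genes of granule cell progenitors and the sonic hedgehog response 7 fell and 3 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.196). Pax6, a transcription factor of the granule lineage, fell from 134 ± 6.66 to 25.3 ± 2.84 CPM, and the hedgehog co-receptor Boc and the homeobox gene Barhl1 fell 3.23-fold and 2.48-fold. The D-type cyclins Ccnd2 and Ccnd1 rose 2.61-fold and 1.68-fold; the hedgehog transducer Smo, at 1.45-fold, lost its call without WT replicate 3, EED-/- replicate 1 or EED-/- replicate 2. Of 6 markers of unipolar brush cells, excitatory interneurons of the granular layer, 4 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.116). Calb2, which the granule neuron list also holds, fell 3.65-fold and Eomes 2.3-fold. Nmb was also called lower, and without WT replicate 1, EED-/- replicate 1 or EED-/- replicate 2 only 2 markers were lower, as also with upper-quartile scaling and library size alone; without WT replicate 1, 1 was higher.

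Markers of Purkinje cells, the output neurons of the cerebellar cortex, were for the most part not called. Of 26 tested 4 were lower and 0 higher over all genes, and 1 was lower adjusted over the list alone, with a median log2 change of 0.07 (camera adjusted p = 0.821). Lhx1 fell 1.7-fold, from 53.9 ± 9.42 to 31.7 ± 1.62 CPM. The calls of Gng13 and Pvalb were lost in several settings: with upper-quartile scaling or library size alone 2 Purkinje markers were higher and 1 lower. DESeq2 called 3 higher and 4 lower, and RLE size factors gave 1 higher and 3 lower. Without WT replicate 1 there were 4 higher and 1 lower. Lower markers numbered 2 without WT replicate 2 or EED-/- replicate 3, and 1 without EED-/- replicate 1 or 2; 1 was higher without WT replicate 2. Among 17 markers of inhibitory interneurons 6 fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.196). Kit, a receptor of molecular layer interneurons, fell from 114 ± 11.2 to 44.6 ± 1.93 CPM, and Cdh22 and Tfap2a fell 2.38-fold and 2.33-fold. Gad2, an enzyme of GABA synthesis, rose 1.89-fold; the rise of Nxph1 was not called without EED-/- replicate 1, which left 1 marker higher. Of 10 markers of the cerebellar nuclei 5 rose and 0 fell (6 adjusted over the list alone; camera adjusted p = 0.00202, and adjusted p = 0.148 with an estimated correlation). The homeobox genes Lhx2 and Meis2 rose 3.74-fold and 2.27-fold and the neurofilament Nefm 1.62-fold. Nefh and the glutamate transporter Slc17a6 made up the 5, and 3 were called without WT replicate 3, EED-/- replicate 2 or EED-/- replicate 3. Of 15 markers of neighbouring brainstem and midbrain neurons 4 rose and 0 fell, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00244, and adjusted p = 0.178 with an estimated correlation). The 4 were Pou4f1 (5.67-fold), Isl1 (3.67-fold), and the monoamine genes Slc18a2 (2.15-fold) and Ddc (2.05-fold); DESeq2 called 7 higher.

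Microglial markers rose together: 15 of 17 were higher and 0 lower, and all 17 were higher adjusted over the list alone. The median log2 change was 0.96 (camera adjusted p = 2.28e-09, and adjusted p = 0.148 with an estimated correlation). Fcrls rose from 11.4 ± 0.309 to 29 ± 2.5 CPM, the fractalkine receptor Cx3cr1 from 26.7 ± 1.44 to 51.6 ± 3.62 CPM, and Trem2, a receptor of phagocytic microglia, from 4.25 ± 0.44 to 11.1 ± 1.66 CPM. Of 20 genes of reactive glia 10 rose and 0 fell (14 adjusted over the list alone; camera adjusted p = 1.54e-06, and adjusted p = 0.206 with an estimated correlation). Complement C4b rose 4.2-fold, from 12.7 ± 0.681 to 53.2 ± 11.8 CPM, and the cytokine receptor Osmr 2.61-fold. Of 22 markers of Bergmann glia and astrocytes 6 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.54). The glutamate transporter Slc1a3 fell from 1202 ± 96.3 to 429 ± 17 CPM and Gdf10, a marker of Bergmann glia, from 311 ± 75 to 87.3 ± 17.5 CPM. Gfap, the intermediate filament of reactive astrocytes, rose from 321 ± 33.7 to 716 ± 252 CPM. Ntsr2 and Gja1 were the other two higher, and without EED-/- replicate 1 or 2 only 1 marker was higher.

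Oligodendrocyte progenitor markers rose in 9 of 13 cases and fell in 0, the same adjusted over the list alone (camera adjusted p = 6.57e-05, and adjusted p = 0.205 with an estimated correlation). Sox6 rose from 26.5 ± 2.11 to 50 ± 3.5 CPM and the growth factor receptor Pdgfra from 71.8 ± 2.7 to 106 ± 5.92 CPM. Without WT replicate 3 or EED-/- replicate 1 the higher markers numbered 3, and without EED-/- replicate 2 they numbered 4. Of 20 genes of myelinating oligodendrocytes 4 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.0839). Opalin fell 2.23-fold and the myelin glycoprotein Mog from 284 ± 6.43 to 185 ± 14.5 CPM. Mal and Mobp were the other two, and 2 were called with upper-quartile scaling and without WT replicate 3 or EED-/- replicate 1. Of 14 markers of meningeal fibroblasts 13 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 4.31e-06, and adjusted p = 0.199 with an estimated correlation). Collagen Col3a1 rose from 41 ± 4.81 to 111 ± 28.5 CPM and the growth factor Igf2 from 186 ± 8.43 to 487 ± 92.3 CPM, while Cemip fell 2.67-fold. Among 20 genes of endothelium and mural cells 7 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00393, and adjusted p = 0.335 with an estimated correlation). Itm2a and smooth muscle actin Acta2 rose 1.54-fold and 1.9-fold, and the tight junction gene Ocln fell 1.63-fold. The higher genes numbered 11 with upper-quartile scaling, 2 without WT replicate 3 or EED-/- replicate 2 and 3 without EED-/- replicate 1. Of 17 choroid plexus and ependymal genes 2 were higher (Foxj1 and Tmem212) and 1 lower (Rarres2), and 0 were called adjusted over the list alone (camera adjusted p = 0.786). The lower call ended with each other scaling and with DESeq2. Leaving out single libraries gave 0 to 2 higher, and 0 lower except 3 without EED-/- replicate 3. Of 6 blood genes edgeR called 0 over all genes and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05, and limma-voom called 0. DESeq2, run without edgeR's low-count filter and so open to further blood genes, called 2. The median log2 change was 1.52 (camera adjusted p = 0.0303, and adjusted p = 0.491 with an estimated correlation). The mean log2 CPM of the blood genes was 7.04, 6.36 and 5.08 in EED-/- replicates 1, 2 and 3 and 5.43, 4.46 and 4.62 in WT replicates 1, 2 and 3. Blood genes called higher numbered 5 without EED-/- replicate 3, 2 without EED-/- replicate 2 and 1 without WT replicate 2. The camera call of this list ended with upper-quartile scaling, with library size alone, and without WT replicate 2 or EED-/- replicate 1.

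**Figure D2:**
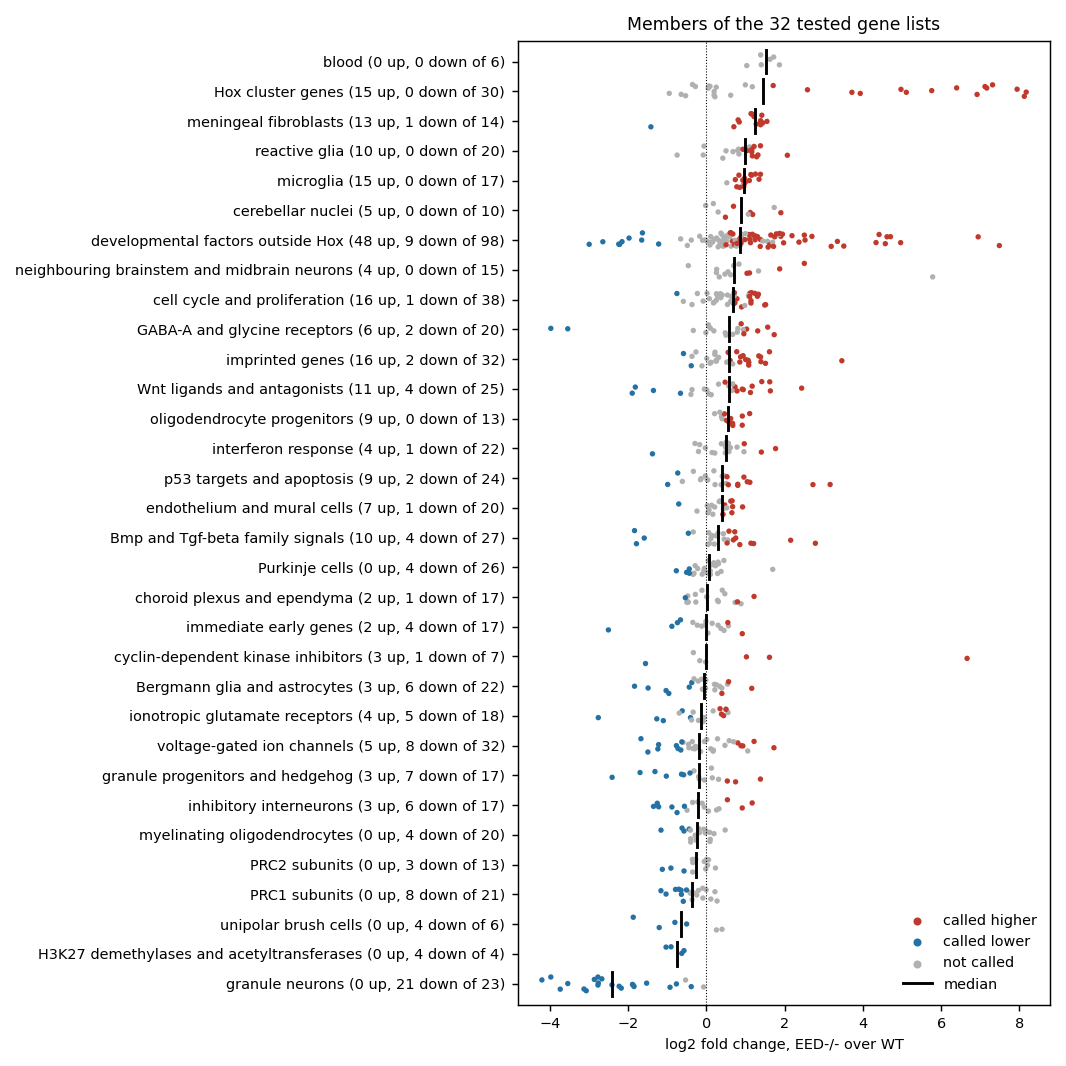
Log2 fold change of EED-/- over WT for every tested member of the 32 lists, in order of the list median (black line); red and blue points passed the edgeR test as higher or lower and grey points did not. Granule neuron markers lie furthest to the left, with 21 of 23 lower and a median of -2.41, and 15 of 17 microglial markers are higher.

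Homeobox genes of the Hox clusters, which set identity along the body axis and are known targets of Polycomb repression, were 15 higher and 0 lower of 30 tested (17 higher adjusted over the list alone); 1 was lower without WT replicate 2. The median log2 change was 1.44, also with genes at 0 counts in WT set to their bound (camera adjusted p = 4.14e-09, and adjusted p = 0.18 with an estimated correlation). Hoxa7 (chromosome 6, 52214491 to 52221854) rose from 0.0873 ± 0.0313 to 2.92 ± 0.573 CPM (log2 fold change 4.97, SE 0.382, adjusted p = 0.00011), and Hoxc8 from 1 to 80 counts. Hoxa9, Hoxa10, Hoxb9 and Hoxb13, named after their values were seen, had 0 counts in WT and were at least 16.5-fold, 18.9-fold, 14.3-fold and 17.1-fold higher. Of 98 developmental transcription factors outside the Hox clusters 48 rose and 9 fell (58 and 11 adjusted over the list alone), with a median log2 change of 0.87 (camera adjusted p = 2.04e-10, and adjusted p = 0.148 with an estimated correlation). The members that fell included factors of the cerebellum itself: En2 fell from 136 ± 26.3 to 21.8 ± 0.692 CPM, and Bhlhe22, Zic4 and Zic5 fell 3.93-fold, 3.14-fold and 4.65-fold. The sensory neuron factor Pou4f1, which the brainstem list also holds, rose from 1.97 ± 1.07 to 11.1 ± 2.05 CPM, and En1 rose 2.13-fold.

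**Figure D3:**
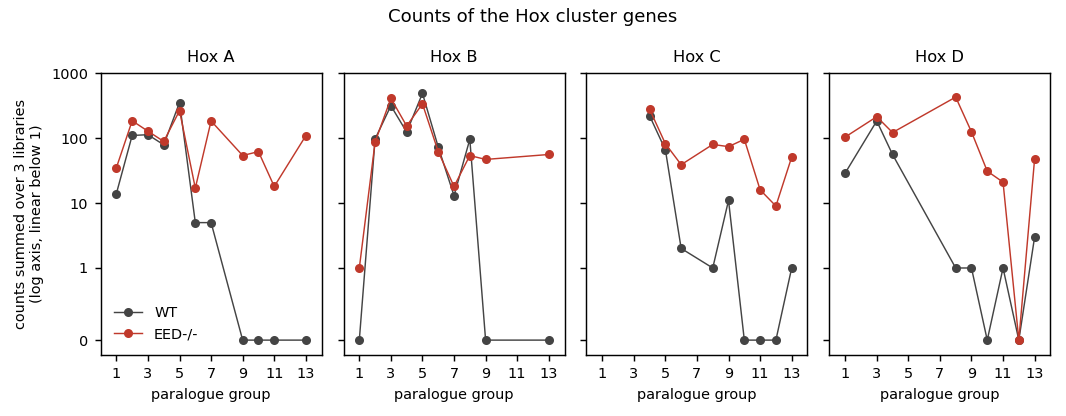
Counts summed over the 3 libraries of each genotype for each of the 39 Hox genes by cluster and paralogue group, on a log axis that is linear below 1, WT in grey and EED-/- in red. In groups 6 to 13 the sums were 213 counts in WT and 1700 in EED-/-, and in groups 1 to 5 they were 2253 and 2493.

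Among genes of the Polycomb machinery and enzymes acting on H3K27, every called gene was lower, although most Polycomb subunits were not called. Of 13 PRC2 subunits 3 fell and 0 rose, the same adjusted over the list alone, with a median log2 change of -0.27 (camera adjusted p = 0.0864). Besides Eed these were Jarid2 and Ezh1. Jarid2, a PRC2 cofactor, fell from 146 ± 6.03 to 78.2 ± 1.67 CPM. The catalytic subunit Ezh1 was 1.48-fold lower, a call that ended without EED-/- replicate 1 or 2. Eed is the targeted gene, so its fall follows from the design, and it also enters the list p-value. Without Eed the lower share of PRC2 subunits was near that of all tested genes, 2544 of 18091. Of 21 PRC1 subunits 8 fell and 0 rose (11 lower adjusted over the list alone; camera adjusted p = 0.00323, and adjusted p = 0.148 with an estimated correlation). Pcgf2, Phc2 and Cbx8 fell 2.04-fold, 2.24-fold and 1.56-fold. Lower PRC1 genes numbered 5 without WT replicate 3 and 4 without any single EED-/- replicate. The H3K27 demethylases Kdm6b and Kdm6a fell 2.04-fold and 1.87-fold, and the H3K27 acetyltransferases Crebbp and Ep300 1.55-fold and 1.49-fold, so that 4 of 4 were lower, also adjusted over the list alone. The camera adjusted p of these 4 was 0.0049, and the adjusted p was 0.148 with an estimated correlation.

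Cell cycle inhibitors moved in both directions, and among cell cycle genes more were higher than lower, although most were not called. Of 7 cyclin-dependent kinase inhibitors 3 were higher and 1 lower, the same adjusted over the list alone, and the median log2 change of -0.02 and the mean of 1.03 differed in sign (camera adjusted p = 0.273). Besides Cdkn2a, the imprinted Cdkn1c rose from 17.6 ± 2.01 to 53.7 ± 10.1 CPM, while Cdkn1b, which encodes p27Kip1, fell from 154 ± 11 to 52.3 ± 4.74 CPM; 2 inhibitors were lower without WT replicate 2. Cdkn2b was 2.03-fold higher, a call that ended without EED-/- replicate 1 or 2. Of 38 cell cycle and proliferation genes 16 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 change of 0.67 (camera adjusted p = 4.31e-06, and adjusted p = 0.205 with an estimated correlation). Topoisomerase Top2a rose from 9.4 ± 0.397 to 23.2 ± 4.65 CPM, cyclin Ccnb1 2.21-fold and the mitotic kinase Cdk1 2.51-fold, while E2f1 was 0.594 of its WT level. The higher genes numbered 8 without WT replicate 3 or EED-/- replicate 1 and 7 without EED-/- replicate 2, and the E2f1 call ended without EED-/- replicate 1 or 3. Among 24 p53 targets and apoptosis genes 9 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0049, and adjusted p = 0.148 with an estimated correlation). The p53-induced receptor Eda2r rose from 0.903 ± 0.0882 to 8.15 ± 1.05 CPM, the BH3-only gene Pmaip1 6.61-fold and Ccng1 1.94-fold. The BH3-only gene Bcl2l11 fell 1.98-fold, and the other lower gene, Bbc3, lost its call with upper-quartile scaling, with library size alone and without any single library but WT replicate 2, which left 1 lower. Without WT replicate 2 there were 4 lower genes, and without EED-/- replicate 1 there were 4 higher.

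Imprinted genes, many of which act in prenatal growth, rose in 16 of 32 cases and fell in 2 (17 and 2 adjusted over the list alone; camera adjusted p = 4.31e-06, and adjusted p = 0.148 with an estimated correlation). The noncoding RNA H19 rose from 7.5 ± 0.813 to 82.7 ± 11.8 CPM (log2 fold change 3.46, SE 0.154, adjusted p = 3.66e-05), its neighbour Igf2 2.61-fold and the growth receptor adaptor Grb10 1.83-fold. H19, Igf2 and Cdkn1c share the distal part of chromosome 7, H19 at 142575529 to 142578143. Peg13 and Kcnk9 were the 2 lower genes; 0 were lower with upper-quartile scaling, and 1 with RLE size factors or library size alone. The lower count was 1 without WT replicate 1 or WT replicate 3, and 0 without any single EED-/- replicate. Of 25 Wnt ligands and antagonists 11 were higher and 4 lower (13 and 5 adjusted over the list alone; camera adjusted p = 0.0253, and adjusted p = 0.259 with an estimated correlation). The antagonist Sfrp2 rose 2.67-fold, while Wnt7a, Frzb and Wif1 fell 3.72-fold, 3.52-fold and 2.55-fold; Sfrp4, the other lower gene, lost its call under most alternatives. The higher genes numbered 7 without WT replicate 3 or EED-/- replicate 1, and the camera call ended with upper-quartile scaling, with library size alone and without WT replicate 2. Of 27 Bmp and Tgf-beta family signals 10 were higher and 4 lower (11 and 4 adjusted over the list alone; camera adjusted p = 0.0216, and adjusted p = 0.205 with an estimated correlation). Bmp7 rose 2.31-fold, and the Bmp antagonist Chrd and the protease Bmp1 fell 3.45-fold and 3-fold, beside Gdf10 and Smad7. The camera call of this list ended without WT replicate 3, and the Smad7 call with upper-quartile scaling.

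Receptors and channels changed in both directions. Among 20 GABA-A and glycine receptor subunits 6 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0243, and adjusted p = 0.576 with an estimated correlation). The 2 lower subunits were Gabrd and Gabra6, which the granule neuron list also holds, while Gabra5 and Gabrg3 rose 2.48-fold and 2.97-fold. Without WT replicate 2 there were 10 higher, and the camera call ended with upper-quartile scaling, library size alone, DESeq2, and without WT replicate 1 or EED-/- replicate 3. Of 18 ionotropic glutamate receptor subunits 5 were lower and 4 higher (6 and 4 adjusted over the list alone; camera adjusted p = 0.509), a balance that turned to 3 lower and 4 higher with upper-quartile scaling. Grin2c, Gria4 and Grik2 fell 6.78-fold, 2.14-fold and 2.4-fold; the calls of Gria1 and Grin1 ended with upper-quartile scaling. The higher subunits Grik1, Grin3a, Grik4 and Grid1 rose 1.27-fold to 1.42-fold; 0 were called without WT replicate 3 or EED-/- replicate 1, and 1 without EED-/- replicate 2. The lower subunits numbered 3 without WT replicate 1, WT replicate 3, EED-/- replicate 1 or EED-/- replicate 2. Of 32 voltage-gated ion channels 8 fell and 5 rose (11 and 7 adjusted over the list alone; camera adjusted p = 0.412), or 7 and 7 with upper-quartile scaling; DESeq2 called 9 higher. The calcium channels Cacna1a, Cacna1d and Cacna1e fell 2.36-fold, 2.33-fold and 3.18-fold and the potassium channel Kcnc1 2.82-fold. The sodium channel Scn3a rose 3.31-fold, Cacna1h 2.33-fold and Kcnc2 1.91-fold; Kcna4 lost its call without EED-/- replicate 1 or 3.

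Of 17 immediate early genes, which follow neuronal activity, 4 were lower and 2 higher (4 and 3 adjusted over the list alone; camera adjusted p = 0.786), or 2 lower and 3 higher with upper-quartile scaling. Egr4 fell from 4.18 ± 1.38 to 0.732 ± 0.105 CPM and the phosphatase gene Dusp1 1.84-fold. The other calls, Nr4a2 and Ier2 lower and Arc and Bdnf higher, each ended when at least 1 library was left out, and 2 were lower without EED-/- replicate 1 or 3. The higher genes numbered 0 without WT replicate 3 or EED-/- replicate 1 and 1 without each of the other libraries in turn. Of 22 interferon response genes 4 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0138, and adjusted p = 0.178 with an estimated correlation). Stat2, a transcription factor of interferon signalling, fell from 66.5 ± 4.03 to 25.6 ± 1.73 CPM. The rises of Ifit2, Ifi27, Mx1 and Rsad2 were each lost when some libraries were left out: 2 were higher without WT replicate 1 or EED-/- replicate 2, 1 without WT replicate 3 and 0 without EED-/- replicate 1. With upper-quartile scaling 7 were higher, and the camera call of this list ended with DESeq2. Of the sex-linked genes only Xist was tested, at 986 ± 318 CPM in WT and 784 ± 90 CPM in EED-/- (adjusted p = 0.319; called lower without WT replicate 1). Every library held 13120 to 24409 Xist counts and 5 to 18 counts of Y-linked genes.

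The authors' deposited table of differences called 4480 genes, 2125 higher and 2355 lower. Of the 4418 among the genes tested here, 4123 (93.3%) were also called in the same direction by edgeR, 0 in the opposite one, and 546 were called only by edgeR. The authors' deposited table gave log2 fold changes of -1.1 for Eed, 6.92 for Cdkn2a, -3.52 for Gabra6 and 3.49 for H19. It rests on the same libraries and is not independent.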

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

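The length and GC corrections were chosen after the data were examined; all other alternatives were fixed before. Eed was called lower under every alternative run, with log2 changes from -1.18 to -1.01. The 2125 higher and 2544 lower genes became 1044 and 832 with a log2 change beyond 1, and 938 and 1222 with an adjusted p under 0.01, as stricter thresholds must. With the GC trend removed calls increased in both directions, to 3056 higher and 3924 lower genes. The lower genes included 7 PRC2 subunits, 14 PRC1 subunits, 8 myelin genes and 13 voltage-gated channels. Among the higher genes were 12 endothelial and mural genes and 10 GABA-A and glycine receptor subunits. The cause of this increase was not tested. Leaving out each library in turn gave 1205 to 2176 higher and 1335 to 2476 lower genes, where fewer samples entered the fit. Apart from the stricter thresholds, the share of the 4669 calls made again in the same direction ran from 53.1% without EED-/- replicate 1 to 99% with the GC trend removed, and was 88% with DESeq2 and 97.4% with limma-voom. Of the 20 lists past the camera threshold 0 passed with an estimated correlation, and the cause was not tested; 5 of the 20 fell short under at least 1 other alternative, and 8 other lists passed in at least 1. The direction of the list test turned for lists that were past the threshold in no setting. For Purkinje cells fry, which does not compare the list with other genes, gave the other direction than camera (median log2 change 0.074), and camera's direction turned without WT replicate 3 or EED-/- replicate 3, with medians of 0.009 to 0.22 when libraries were left out. For choroid plexus and ependyma it turned without EED-/- replicate 3, in a range of -0.293 to 0.185, and for immediate early genes without WT replicate 1 or EED-/- replicate 1, in a range of -0.023 to 0.149. The cause was not tested. Of 193 called genes taken by the rule or named later, 143 kept the call under each other scaling, filter and tool, the replicate block, each left-out library and without mitochondrial genes, where tested; the stricter thresholds and the length and GC corrections were not run gene by gene. Of the rest, 50 lost it when at least 1 library was left out, 19 lost it under another scaling, and 0 changed sign. At this depth a 2-fold change was found for 59% of simulated genes, so genes not called may still differ. The simulation changed only 200 of 17725 genes, far fewer than the 4669 called here. The adjusted p depends on that share, so the 59% is not the sensitivity of this comparison. The alternatives for normalized values, a pseudocount and a low-value filter, were not run, since the values are counts.

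No pairing of the libraries by replicate number was seen. Same-numbered libraries had correlations of their deviations from the group means of 0.028, -0.233 and -0.001. WT replicate 1 correlated more with EED-/- replicate 2 (0.181) and WT replicate 2 with EED-/- replicate 3 (0.198). Deviations from a mean of 3 libraries depend on each other, so these values cannot exclude a pairing, and the labels do not state one. With the replicate block the fit called 1505 higher and 1706 lower genes, 3211 in all, and 20 lists.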

Other observations

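The gene lists of this part, the tests of muscle and microglial markers and the grouping of Hox genes were chosen after the data were examined; the length and GC corrections were added after the data were examined but before their own results were seen. Genes of skeletal muscle rose almost without exception: of 38 tested 36 were higher and 0 lower, the same adjusted over the list alone, with a median log2 change of 3.42 (camera adjusted p = 9.54e-27 over the 6 added lists, and adjusted p = 0.0669 with an estimated correlation). The list was written after muscle genes were seen among the largest rises and holds those genes, Myh3, Myh8, Ckm, Chrng and Chrnd, so these p-values in part restate that observation and are not independent evidence. The myogenic regulator Myog rose from 0.07 ± 0.0606 to 2 ± 0.705 CPM and Mymk, needed for myoblast fusion, from 0.14 ± 0.0799 to 1.47 ± 0.552 CPM. The 2 genes not called were Neb and another myogenic regulator, Myod1. Myod1 was at 0.451 ± 0.143 CPM in WT and 0.696 ± 0.329 CPM in EED-/- (adjusted p = 0.362 by edgeR). Myoglobin (Mb) rose from 0.312 ± 0.177 to 13.1 ± 1.95 CPM, skeletal actin Acta1 from 1.7 ± 0.198 to 21.9 ± 3.98 CPM and the slow myosin Myh7 from 3.28 ± 0.575 to 33.5 ± 4.33 CPM (SD, n = 3).

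Genes described in activated or disease-associated microglia were 9 higher and 1 lower (Ank) of 19 tested, with 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.72e-05, and adjusted p = 0.314 with an estimated correlation). The integrin Itgax rose from 0.242 ± 0.0747 to 3.33 ± 2.77 CPM, Clec7a from 0.368 ± 0.192 to 3.47 ± 2.61 CPM and Igf1 from 10.7 ± 4.08 to 30.9 ± 4.99 CPM, with a wide spread of Itgax and Clec7a among the EED-/- libraries. The call of Ank ended with upper-quartile scaling, with library size alone, with either other low-count filter, with the replicate block and without any single library but WT replicate 2. Of the 19 genes 16 reached 1 CPM in WT cerebellum and 3 are also in a fixed list. Among 13 genes of the isthmus, the signalling centre that patterns the cerebellum, 5 were higher and 2 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.462). Cnpy1 fell from 261 ± 64 to 41.2 ± 11.7 CPM beside En2, while Pax5 and Sp8 rose 4.29-fold and 6.31-fold beside En1; the call of Pax8 ended without any single library but EED-/- replicate 1 and that of Gbx2 without any but WT replicate 1. Without WT replicate 2, WT replicate 3 or EED-/- replicate 2 only 3 isthmus genes were higher; 6 of the 13 are also in a fixed list. Of 11 germline genes only Prm1, a protamine of sperm chromatin, was called: it rose from 0.192 ± 0.032 to 7.86 ± 1.5 CPM (39.8-fold, adjusted p = 3.66e-05 by edgeR; 1 higher adjusted over the list alone; camera adjusted p = 0.462). Without WT replicate 2, 2 germline genes were higher. Of 66 nuclear-encoded respiratory chain genes edgeR called 0, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 and a median log2 change of 0.01 (camera adjusted p = 0.462). DESeq2, which tested 67, called 1 lower, limma-voom called 0, and edgeR called 1 higher without EED-/- replicate 3. Of 20 cholesterol synthesis genes 2 were lower and 0 higher, and 0 were called adjusted over the list alone (camera adjusted p = 0.714). Among them was Ebp, whose call ended with each other scaling, with DESeq2 and without any single library but WT replicate 2.

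The Hox genes differed by paralogue group, a grouping chosen after their values were seen and not tested. Of 14 tested genes of groups 1 to 5, which the hindbrain next to the cerebellum expresses, 1 was called (Hoxd1, 3.27-fold higher). Over all 15 genes of these groups the counts of 3 libraries summed to 2253 in WT and 2493 in EED-/-. Of 16 tested genes of groups 6 to 13, which act in the trunk and limbs, 14 were called higher, and over all 24 genes of these groups, tested or not, the sums were 213 and 1700. Many of the called genes had few or no WT counts and entered the test through their EED-/- counts.

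Skeletal muscle genes were weighed for origin; of the 38, 17 reached 1 CPM in WT cerebellum and 0 are in a fixed list. Stray mature fast muscle brings the myosins Myh1, Myh2 and Myh4. In the EED-/- libraries their summed CPM was at most 0.0461 of that of the embryonic and perinatal Myh3 and Myh8. This argues against mature fast muscle as the whole source. It does not exclude it as a part, since the summed CPM of Myh1, Myh2 and Myh4 also rose. It was 0.154, 0.268 and 0.413 in WT and 1.8, 3.06 and 1.42 in EED-/- replicates 1, 2 and 3. Mature slow muscle is not addressed, since its myosin Myh7 reached 33.5 CPM and Car3 23.3 CPM in EED-/-, nor is other tissue: mean log2 CPM was higher in EED-/- by 1.02 for meningeal, 1.13 for brainstem and midbrain and, with overlapping libraries, 1.32 for blood markers. A smaller granule cell share would raise all other transcripts alike. The muscle median, however, exceeded the Purkinje median by 3.34 on the log2 scale, against a larger member SD of 1.85. Both medians were known when this comparison was chosen, so it restates their difference. The SD is over member genes, not libraries, and whether Purkinje cells were unchanged was not tested. Slow or immature muscle or other tissue carried along in dissection and expression of muscle genes by cerebellar cells stay open, as untested, since bulk RNA does not show which cells hold these transcripts.

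Lists of microglia, meninges and oligodendrocyte progenitors were past the camera threshold as higher and those of Purkinje cells, astroglia and myelin were not, but with an estimated correlation the first 3 had adjusted p = 0.148, 0.199 and 0.205. Oligodendrocyte progenitor genes called higher fell from 9 of 13 to 3 without WT replicate 3 or EED-/- replicate 1 and to 4 without EED-/- replicate 2. A smaller granule cell share would raise the markers of all other cell types alike, but the microglial minus Purkinje score (mean log2 CPM of the members) rose by 0.92, from -3.87 in WT to -2.94 in EED-/-, with a larger group SD of 0.15 and no overlap between libraries. The list medians were known when this score was chosen, so it restates that both lists did not move alike. A change in microglia, in Purkinje cells or in both, in number or in expression per cell, may account for the difference. These parts cannot be separated in bulk tissue. A lower granule cell share could still add to each rise.

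The 25 PRC1 and H3K27 enzyme genes, of which 12 were lower, have long transcripts, with a median of 5179 bases against 3152 for all tested genes. The median log2 change of these 25 genes was -0.41 (SD 0.39), and it was -0.45 with the length trend and -0.47 with the GC trend of each library removed, with 12, 13 and 18 genes called lower. This argues against either trend as the whole cause. A lower share of granule neuron RNA and regulation in the remaining cells stay open, as untested.

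The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4669 genes and the highest of the others 1; in 1 of the 10 splits, the real one, was the count as large. For the lists the real split gave 20 and the others 2 to 17, and again 1 of the 10 splits was as large. The splits with 17 and 16 lists called 0 genes each, so many lists can pass at the preset correlation where single genes do not. These splits are uneven in genotype, so their list calls may in part come from genotype, which was not tested. The list p-values at that correlation are therefore weak evidence by themselves.

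Of 154 tested genes within 10 Mb of Eed 36 were called, or 23.4% (95% exact interval 16.9 to 30.9%), against 25.9% of other autosomal genes (Fisher's exact two-sided p = 0.518). Away from Eed, which lies on chromosome 7, some gene models were counted in 1 genotype only. Gm10184 on chromosome 17 had 534 counts over the WT libraries and 0 in EED-/-. Gm50367, also on chromosome 17, had 185 and 0, and Gm10401 on chromosome 5 had 0 and 118.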
